A study of Equus caballus with 12 samples.

How the data were processed

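Transcript levels were measured on 12 one-colour microarrays, with biotin-labelled cDNA, in alveolar macrophages from 6 Standardbred horses, each sampled before training (T0) and again in training (T1). Per the labels, the samples are alveolar macrophages, although their shared culture protocol names peritoneal as well as bronchoalveolar lavage, and all were taken here as alveolar. The cells were plated overnight in medium with 10% horse serum, and the cells that did not stick to the plastic were washed away. Alveolar macrophages are the resident phagocytes of the air spaces, and adherence enriches for them without sorting, so other cell types can remain. Total RNA (50 ng per sample) was amplified, and 2.5 µg of the product was labelled, per the labels' protocols. The weeks of training per horse are not given in the sources used here. The labels put all T1 samples between 1.5 and 7 weeks, and the series design allows a shorter minimum of at least 1 week.

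The authors deposited a linear intensity for each of 30559 probes on each array. Partek is named in the submitters' processing notes with no version or role. The background correction, the summary over probe sequences and the normalization are not given in the sources used here. Array medians lay between 74.91 and 80.58 and single intensities between 7.739 and 15180, so the arrays had already been brought to a common scale. No pair of arrays held identical values. Of the probes, 16789 carried 1 gene symbol in the platform's gene table (16661 different genes, 111 of them with more than 1 probe), 343 carried several symbols and were not named, and 13427 were not listed there and are unnamed here. Symbols are those of that table. In 412 cases a probe's values repeated those of an earlier probe. No probe was named as a control. Detection calls, scan dates and slide positions were not used here, so no probe could be called above or below background and no scan or slide batch was tested. The number of arrays limits the precision.

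Intensities were taken to log2 after adding a pseudocount of 1, which understates the change of dim probes. T1 was compared with T0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings), with the horse as a block, a two-sided test, and Benjamini-Hochberg adjustment over all 30559 probes at a threshold of 0.05. The block was chosen because the study sampled the same horses at both times. The arrays bore out this pairing. After the mean of each time point was removed, the correlation between arrays of the same horse was 0.216 to 0.553, against -0.284 to 0.13 between arrays of different horses, and 6 of 6 T1 arrays correlated best with the T0 array of their own horse. These correlations are across probes, which are not independent replicates. The fit without the block is among the alternatives.

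On simulated data with 200 of 30559 probes changed, this fit recovered 59.7% of probes changed by 0.5 on the log2 scale. It recovered 89.6% of those changed by 1 and 98.5% of those changed by 2, with 5 false calls among 170. The simulated noise was independent between probes, without the deviations that probes share in real arrays, so these shares may not hold for the real data. The median residual SD was 0.139 log2 units, and the 95% interval of a T1 minus T0 difference had a median width of 0.363.

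The 32 gene lists were fixed from textbook knowledge before the data were examined, as were the tests and the rule for naming genes. The probe with the highest mean stood for a gene. Lists were tested with limma's camera (preset correlation 0.01), which compares a list with all other genes, and adjusted over the 32 lists. Beside it stood camera with an estimated correlation between genes, fry, which asks whether the members move on balance one way (or, in its mixed form, either way) without comparing them with other genes, and an exact two-sided sign-flip test of the list's mean within-horse difference, which has 64 flips and a smallest possible p of 0.03125. In simulated lists of 34 genes with no shift but a shared deviation per array of SD 0.15, the preset correlation called 66% of 50 lists, and the estimated correlation and the sign-flip test each called 6%. With a shift of 0.3 and that shared deviation, the 3 tests called 100%, 54% and 64%. The preset test is therefore open to false calls where members vary together.

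The rule for single genes asked for 12 genes each way past the threshold that moved one way in all 6 horses. If fewer than 5 passed in a direction, it took the 10 with the smallest unadjusted p that moved one way in all 6 horses. The latter form applied in both directions. From each list, the 4 members with the smallest p were taken where the list passed camera, and 2 otherwise. Other genes named below were chosen after their values were seen, and are introduced as such.

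Alternatives were no block, the horse as a random effect (with camera's pre-ranked form for the lists), quantile normalization, centring on array medians, leaving out the dimmest probes (mean log2 level under 5.435), array weights, eBayes with trend and robust settings, a pseudocount of 16, an adjusted p under 0.1, an unadjusted p under 0.05 with at least 1.5-fold change, the mean over a gene's probes, and leaving out each horse. A pair of alternatives was chosen after seeing the data: keeping repeated probes once, and testing only named genes with 1 probe each. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.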

Results

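Alveolar macrophages of 6 Standardbred racehorses were profiled before entry into training (T0, 6 arrays) and during training (T1, 6 arrays), so that each horse served as its own control. The comparison asks how basal gene expression of these cells differs between T0 and T1. No untrained horse was sampled at both times, so training cannot be told apart from the passage of time. Nor can it be told apart from differences in handling between the time points. All 12 arrays gave intensities for 30559 probes, with array medians from 74.91 to 80.58.

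In the T1 preparations, the gene list for T and natural killer (NK) cells had a lower mean than at T0 in 5 of 6 horses. So did the list for mast cells, basophils and eosinophils (exact sign-flip p = 0.0625 for each). No member of either list passed when adjusted over all probes. A second list of mast cell and basophil genes had a smaller mean shift of -0.047, with 11 of 14 genes lower. Gene lists for ribosomal proteins, oxidative phosphorylation, antioxidant defence, lipid handling, phagocytosis and the unfolded protein response were slightly higher at T1. In these list comparisons 10 of 32 lists passed limma's camera with its preset correlation, 6 higher and 4 lower. With an estimated correlation, by fry's one-way form, or by the exact sign-flip test, 0 of 32 passed. The sign-flip test cannot bring 1 list past adjustment by itself, since its smallest p is 0.03125 and many lists would have to reach it. Fry's mixed form, which counts change either way, passed 4 lists. No single probe passed an adjusted p of 0.05 in limma. At an unadjusted p under 0.05 there were 3970 probes, 1775 higher and 2195 lower at T1, against 1528 given by chance. The excess of lower probes lay among those not in the platform's gene table (657 higher, 1175 lower). Probes with 1 gene symbol went the other way (1099 higher, 981 lower).

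The T and NK cell list had the smallest p of all lists. Of its 34 measured genes, 31 were lower at T1 and 23 of these had an unadjusted p under 0.05. Adjusted over the list alone 22 passed, and adjusted over all probes 0 passed. The mean shift was -0.29 ± 0.19 log2 units (SD over 6 horses), with camera adjusted p = 3.94e-15 at the preset correlation and adjusted p = 0.642 with an estimated correlation. That correlation was 0.36, and camera's unadjusted p with it was 0.0439. Adjustment gave the same 0.642 to lists with a larger unadjusted p, such as oxidative phosphorylation (camera, 0.281). The T and NK list was lower in 5 of 6 horses, from -0.24 in horse 3 to -0.52 in horse 4, and 0.05 in horse 2, with an exact sign-flip p = 0.0625. The genes named by rule were EOMES, a transcription factor of cytotoxic lymphocytes (-0.48, SE 0.099), CD247, the zeta chain of the T cell receptor complex (-0.32, SE 0.067), PRF1, which encodes the pore-forming protein perforin (-0.53, SE 0.113), and CD2, an adhesion receptor of T and NK cells (-0.60, SE 0.131). Their limma adjusted p lay between 0.189 and 0.2, so no member passed on its own. CD28 (0.20), CD8B (0.13) and GZMB (0.02), picked out after their values were seen, were the 3 members with a positive difference. Chosen by level alone, outside the naming rule, the brightest members at T0 were IL7R (mean log2 12.71), CCL5 (12.06), CD28 (10.76), CD3D (10.07) and CD2 (10.04). At T1 these were at 12.66, 11.97, 10.95, 9.57 and 9.44. Of the 34 genes, 33 had a mean level above the median of all probes, and 1, CCL5, is also in the cytokine list.

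**Figure D1:**
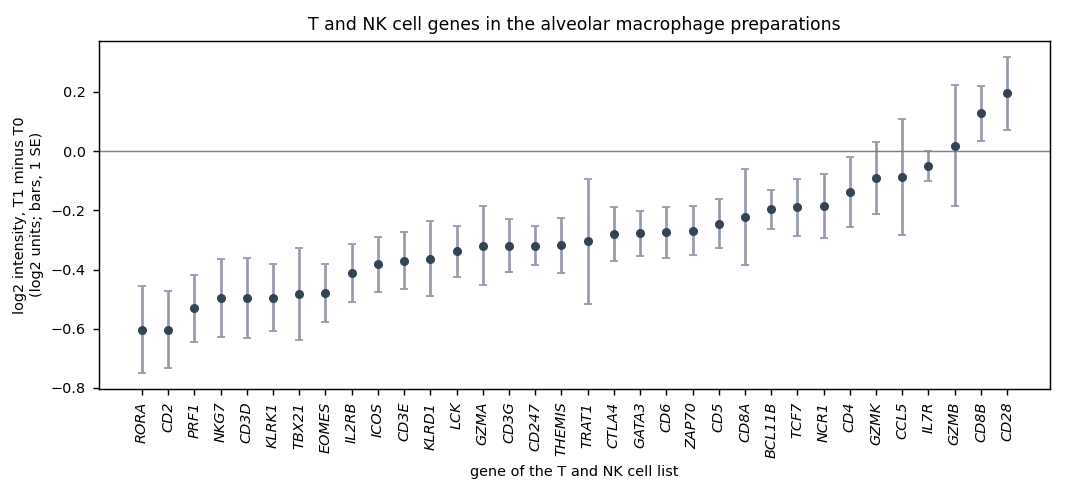
T1 minus T0 difference of log2 intensity (y axis, log2 units) for each of the 34 measured genes of the T and NK cell list (x axis, ordered by value). Points are means over 6 horses and bars are 1 standard error from limma. Of the 34 points, 31 lie below 0.

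The list for mast cells, basophils and eosinophils had 11 measured genes, 10 of them lower at T1 and 7 with an unadjusted p under 0.05. Adjusted over the list alone 4 passed, and over all probes 0 passed. The mean shift was -0.60 ± 0.62 (SD over 6 horses), with camera adjusted p = 4.79e-06 and adjusted p = 0.642 with an estimated correlation. That correlation was 0.46, and camera's unadjusted p with it was 0.0725. Horses differed widely, from -1.51 in horse 4 and -1.10 in horse 2 to 0.11 in horse 3, and the exact sign-flip p was 0.0625. CCR3, the eotaxin receptor of eosinophils and basophils, had a difference of -0.49 (SE 0.075) and was lower in 6 of 6 horses. HDC, which makes histamine, was at -0.47 (SE 0.125), GATA2, a transcription factor of mast cells and basophils, at -0.55 (SE 0.159), and MS4A2, the beta chain of the high-affinity IgE receptor, at -1.52 (SE 0.51), or -1 without horse 4. Limma adjusted p of these 4 genes lay between 0.154 and 0.301. Chosen likewise by level, the brightest members at T0 were MS4A2 (mean log2 9.24), KIT (8.71) and FCER1A (8.64), which were at 7.72, 7.66 and 7.71 at T1.

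The dendritic cell list had a mean shift of -0.18 ± 0.31 (SD over 6 horses; 13 of 17 genes lower, 4 at an unadjusted p under 0.05), with camera adjusted p = 0.0216 and adjusted p = 0.642 with an estimated correlation. The shift was -0.133 without horse 3 (camera adjusted p = 0.232) and -0.0873 without horse 4 (0.097). Adjusted over the list alone and over all probes, 0 passed. CCR7, the receptor that guides dendritic cells to lymph nodes, was at -0.37, its ligand CCL19 at -0.16, XCR1 at -0.26 and FCER1A, which also belongs to the mast cell list, at -0.93, or -0.588 without horse 4. The other lists of foreign cell types did not pass camera. Mean shifts were 0.06 for neutrophils (14 genes, adjusted p = 0.868), with MMP9 at 0.51 and CXCR2 at 0.16, and -0.06 for B and plasma cells (15 genes, adjusted p = 0.245), with TNFRSF17 at -0.18 and CD22 at -0.26. They were -0.09 for airway and alveolar epithelium (27 genes, adjusted p = 0.0797), with DNAH5 at -0.15 and SFTPA1 at -0.16, and -0.04 for fibroblasts and endothelium (15 genes, adjusted p = 0.421), with EMCN at -0.47 and COL1A2 at -0.11. Erythrocyte and platelet genes had a mean of 0.07 and a median of -0.02 (12 genes, adjusted p = 0.763 with the test pointing down), with CA2 at 1.21 and SLC4A1 at -0.13. Single horses weighed heavily in these small shifts. The neutrophil shift was 0.000476 without horse 5 and 0.115 without horse 3, with MMP9 at 0.263 without horse 4 and 0.764 without horse 3, and CXCR2 at 0.0545 without horse 3 and 0.25 without horse 1. CA2 was at 0.735 without horse 4, and CD22 at -0.139 without horse 4 and -0.415 without horse 5. Without horse 4 the shifts were -0.0293 for B and plasma cells, -0.0488 for epithelium, -0.0225 for fibroblasts and endothelium (-0.0648 without horse 5) and 0.0394 for erythrocytes and platelets (0.132 without horse 3).

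The lists for cell functions come next. The cells were not sorted, so whether their shifts lie within macrophages or follow the mix of cell types was not tested. Cytosolic ribosomal proteins were higher at T1 for 49 of 60 genes (mean 0.09 ± 0.13, SD over 6 horses; camera adjusted p = 0.000225, adjusted p = 0.683 with an estimated correlation), with RPS15A at 0.28, RPS4X at 0.27, RPL7A at 0.21 and RPL22 at 0.19. Oxidative phosphorylation genes were higher for 30 of 37 (mean 0.08 ± 0.12, SD; adjusted p = 0.0018, adjusted p = 0.642 with an estimated correlation). The examples were NDUFA1 (0.35, the 1 gene that passed when adjusted over the list alone), NDUFB5 (0.27) and NDUFA8 (0.23) of complex I and ATP5F1A (0.17) of ATP synthase. In both lists horse 1 had the largest shift, 0.32 and 0.28. Without horse 1 the ribosomal shift was 0.0397 (adjusted p = 0.211) and the oxidative phosphorylation shift 0.0448 (adjusted p = 0.104).

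Antioxidant and NRF2 target genes were higher for 15 of 18 (mean 0.10 ± 0.11, SD; camera adjusted p = 0.0182, adjusted p = 0.642 with an estimated correlation). GCLM, a subunit of the enzyme that starts glutathione synthesis, was at 0.32, PRDX6 at 0.33 (0.196 without horse 4), HMOX1, which breaks down haem, at 0.23 and TALDO1 at 0.20. Unfolded protein response genes were higher for 16 of 22 (mean 0.07 ± 0.11, SD; adjusted p = 0.0208, adjusted p = 0.642 with an estimated correlation). CRELD2 (0.37, SE 0.068), MANF (0.25), PDIA4 (0.25) and SDF2L1 (0.16), which act on proteins in the endoplasmic reticulum, were each higher in 6 of 6 horses, and 1 gene of this list passed when adjusted over the list alone. The antioxidant call ended without horse 1 (camera adjusted p = 0.0857) or horse 3 (0.0506), and the unfolded protein response call without horse 2 (shift 0.0449, 0.117) or horse 5 (0.0563).

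Lipid uptake, efflux and PPAR target genes were higher for 22 of 26 (mean 0.10 ± 0.13, SD; camera adjusted p = 0.0208, adjusted p = 0.642 with an estimated correlation), with the desaturase SCD at 0.21, PDK4 at 0.29, the cholesterol exporter ABCG1 at 0.34 and the lipase LPL at 0.35 (0.188 without horse 4). Phagocytosis, Fc and complement receptor genes were higher for 16 of 19 (mean 0.11 ± 0.12, SD; adjusted p = 0.0216, adjusted p = 0.642 with an estimated correlation). AIF1 was at 0.38, the scavenger receptor MSR1 at 0.23 and the kinase SYK at 0.27, while RAC2 was at -0.24. The lipid call ended without horse 3 (shift 0.0673, camera adjusted p = 0.262), and the phagocytosis call without horse 3 (0.172) or horse 4 (0.0837). In the antioxidant, lipid, phagocytosis and ribosomal lists, 0 genes passed when adjusted over the list alone.

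Genes of the NF-kappaB pathway and its feedback were lower for 15 of 18 (mean -0.09 ± 0.18, SD over 6 horses; camera adjusted p = 0.0295, adjusted p = 0.72 with an estimated correlation), with 0 passing when adjusted over the list alone. The shift was -0.0519 without horse 3 (camera adjusted p = 0.432), -0.052 without horse 4 (0.097) and -0.0772 without horse 6 (0.119), but -0.143 without horse 1 (0.00109). The inhibitor TNFAIP3 was at -0.30, TRAF1 at -0.27, NFKBIB at -0.17 and NFKBIZ at -0.14. Without horse 4 TRAF1 was at -0.15 and NFKBIZ at -0.0864, and without horse 3 NFKBIB was at -0.112. Inflammatory cytokines and chemokines had a mean of -0.10 (15 of 24 lower; adjusted p = 0.139), with IL10 at -0.68 and OSM at -0.42. Interferon-stimulated genes had a mean of -0.07 and a median of -0.02 (22 of 37 lower, camera adjusted p = 0.443), with the chemokine CXCL9 at -1.25 and IFI6 at 0.18. CXCL11, picked out after its value was seen, was at -0.92, and it and CXCL9 weighed heavily in this mean. In horse 5 both lists were higher, at 0.19 and 0.29, and without it the shifts were -0.154 (adjusted p = 0.0193) and -0.143 (adjusted p = 0.00144). The cytokine list was also higher in horse 2, at 0.22, and without that horse its shift was -0.16 (adjusted p = 0.0158). Other horses carried the lower values. Without horse 3, itself at -0.56, the cytokine shift was -0.00383 (adjusted p = 0.929), and without horse 4, itself at -0.35, the interferon shift was -0.0159 (adjusted p = 0.753). Immediate early genes had a mean of -0.06 (14 of 21 lower; adjusted p = 0.127), and 3 members passed when adjusted over the list alone. Its shift ran from -0.0985 without horse 5 (adjusted p = 0.0223) to -0.0255 without horse 3 (adjusted p = 0.542). The nuclear receptor gene NR4A3 (-0.33) and the phosphatase gene DUSP2 (-0.32) were lower in 6 of 6 horses. Fry's mixed test, which counts change either way, gave adjusted p = 0.00193 for this list, 0.00484 for MHC class II, 0.034 for the unfolded protein response and 0.034 for T and NK cells.

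The remaining lists did not pass camera. The mean shift was 0.15 for recently recruited macrophages (adjusted p = 0.868), with CCR2 at -0.56 and CLEC5A at 1.11, and 0.11 for alternative activation and tissue repair (adjusted p = 0.174), with CD9 at 0.55 and TGFBI at 0.58. Lysosome and protease genes were at 0.09 (adjusted p = 0.127), with the elastase gene MMP12 at 1.02 and CTSC at -0.18. Pattern recognition and inflammasome genes were at 0.08 (adjusted p = 0.0744), with NLRP3 at 0.46 and TLR6 at 0.28, and the alveolar macrophage identity list at 0.08 (adjusted p = 0.421), with CSF1R at 0.42 and MSR1 at 0.23. Haem and iron handling was at 0.05 (adjusted p = 0.279), with LRP1 at 0.27 and TFRC at -0.30. Cholesterol synthesis was at -0.06 (adjusted p = 0.279), with SREBF2 at -0.17 and HMGCS1 at -0.20, but single horses decided it, at 0.00509 without horse 5, -0.115 without horse 2 (adjusted p = 0.0274) and -0.139 without horse 4 (adjusted p = 0.00215). MHC class I was at -0.06 (adjusted p = 0.254), with CALR at 0.19 and TAPBP at -0.17. MHC class II was at -0.03 (adjusted p = 0.416; 0.00857 after median centring and 0.00963 without horse 3), with its transactivator CIITA at -0.22 and CD74 at -0.19. Leaving out 1 horse also moved other lists. The identity list was at 0.012 without horse 3 and 0.125 without horse 2, recently recruited macrophages at 0.249 without horse 3 and 0.0882 without horse 4, and MHC class I at -0.0181 without horse 4. Pattern recognition was at 0.056 without horse 4, and MHC class II at -0.0538 without horse 2. Among the genes, CLEC5A was at 0.688, NLRP3 at 0.288 and TFRC at -0.184 without horse 4, and MMP12 at 0.655 and TGFBI at 0.382 without horse 5. Without horse 6 SREBF2 was at -0.11 and HMGCS1 at -0.112, the latter at -0.295 without horse 2.

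Mean shifts of 0.006 or less in size were found for 5 lists, and each of these turns sign under some setting. They were 0.005 for NADPH oxidase (adjusted p = 0.871; RAC2 -0.24, CYBA 0.15), 0.006 for glucocorticoid response (adjusted p = 0.868; DUSP1 -0.30, KLF9 0.13) and -0.006 for hypoxia and glycolysis (adjusted p = 0.932; ALDOC -0.26, ENO2 -0.16, with a median of 0.03). Heat shock was at -0.004 (adjusted p = 0.868 with the test pointing up and a median of 0.01; HSPA1B -0.42, HSP90B1 0.10) and cell cycle at -0.001 (adjusted p = 0.901 with the test pointing up; RRM2 -0.25, PCNA 0.18). Without horse 4 HSPA1B was at -0.196 and PCNA at 0.0926, and without horse 2 DUSP1 was at -0.171.

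**Figure D2:**
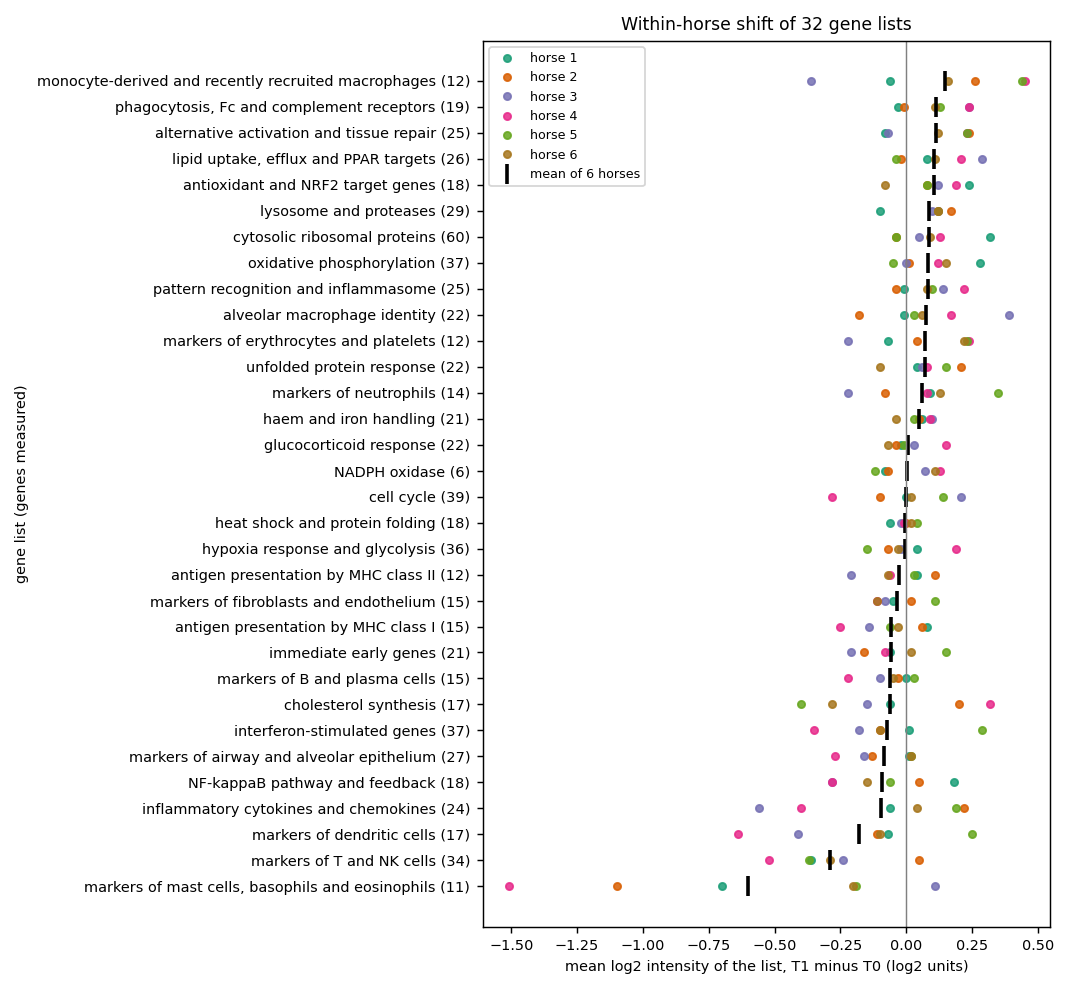
Mean T1 minus T0 difference of log2 intensity (x axis, log2 units) for 32 gene lists (y axis, with the number of genes measured), 1 coloured point per horse and a black bar for the mean of 6 horses. The mast cell list spans -1.51 to 0.11, and the T and NK cell list lies below 0 in 5 of 6 horses.

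Among single genes, MIR223, the gene of a microRNA abundant in myeloid cells, had the smallest p. Its mean intensity was 140 at T0 and 355 at T1, a difference of 1.40 log2 units (SE 0.135, 95% interval 1.09 to 1.71, 2.64-fold). It was higher in 6 of 6 horses, as the naming rule required, and its limma adjusted p was 0.143. Leaving out horse 1 (adjusted p = 0.0369) or horse 5 (adjusted p = 0.0491) brought it past the threshold, within a range of 0.0131 to 0.71 over 14 alternatives. The other 9 genes named on the higher side had differences of 0.33 to 0.44 and adjusted p between 0.154 and 0.18. SELENOS, a selenoprotein of the endoplasmic reticulum (0.44, SE 0.065), MORN2 (0.44) and CRELD2 (0.37) belonged to them, with GDA, a guanine deaminase (0.36), ACYP2 (0.36), UBE2E1, a ubiquitin-conjugating enzyme (0.35), RHBDL2 (0.35), WDR89 (0.35) and ZNF396 (0.33).

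On the lower side, IKZF3, the lymphocyte transcription factor Aiolos, was at -0.59 (SE 0.072, adjusted p = 0.154), LINGO4 at -0.65 (SE 0.088), GRAMD2B at -0.55 (SE 0.071) and the olfactory receptor gene OR52A1I at -0.55 (SE 0.077). NFATC2, a calcium-dependent transcription factor of activated T cells, was at -0.54 (SE 0.096), RIPOR2 at -0.51, CCR3 at -0.49, GLCCI1 at -0.40, LOC100147440 at -0.39 and NR4A3 at -0.33. Adjusted p of these 10 genes lay between 0.154 and 0.18 in limma. Each was lower in 6 of 6 horses, as the naming rule required.

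**Figure D3:**
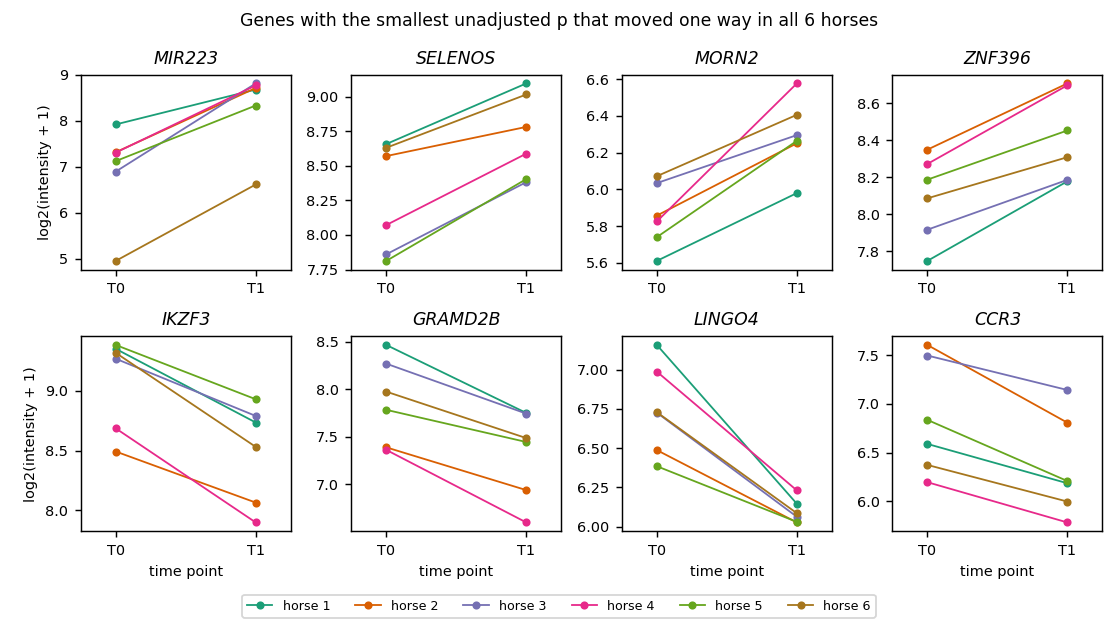
Log2 of intensity plus 1 (y axis, own scale per gene) at T0 and T1 (x axis) for 8 of the 20 genes named by rule, 1 line per horse. As the rule required, every line ends higher at T1 for MIR223, SELENOS, MORN2 and ZNF396 and lower for IKZF3, GRAMD2B, LINGO4 and CCR3. Horse 6 lies below the other horses for MIR223, at 4.95 and 6.61.

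Over all probes, 2251 moved the same way in all 6 horses (1012 higher, 1239 lower), 7.37% against 3.12% by chance. Principal components 1, 2 and 3 held 21.6%, 15.6% and 12% of the variance, and T1 minus T0 had 1 sign in 6 of 6 horses on each (exact sign-flip p = 0.0312, the smallest possible). On component 4, with 11.5%, it had 1 sign in 5 of 6 horses (exact sign-flip p = 0.0938). The balance of the directions depends on scaling. At an unadjusted p under 0.05, 44.7% of probes were higher at T1 as deposited, 49.1% after quantile normalization (1793 higher, 1857 lower) and 65.3% after centring on array medians (2678 higher, 1425 lower).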

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

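The test that set T and NK genes against other foreign cell types and the test on taste and vomeronasal receptors were chosen after the results were seen. So were the counts over swapped time points, except those of gene lists and of probes moving one way. The count of probes moving one way was planned with its comparison over swaps, but the threshold for reading it was set after the results were seen. The 32 lists, the 20 genes named by rule for all probes and the array medians gave 106 groups of 6 arrays to search for an array far from the others, counting each time point by itself, and 4 such values were found. Chance gives about 1 in 20 groups in this test, Dixon's. MIR223 in horse 6 was low at both times, 4.95 at T0 against 6.89 to 7.92 in the other horses and 6.61 at T1 against 8.33 to 8.81. Cell cycle genes of horse 4 at T0 had a mean of 6.84 against 6.44 to 6.56. B and plasma cell genes of horse 2 at T0 had a mean of 6.35 against 6.46 to 6.49. All are log2 intensities.

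The lower T and NK cell list may reflect fewer lymphocytes among the adherent cells. A second list of T and NK genes, written down before its values were seen and sharing no gene with the first, had 36 measured members. All 36 were lower at T1, 21 at an unadjusted p under 0.05, with a mean of -0.323 ± 0.237 (SD over 6 horses), at percentile 0 among 10000 random lists matched on level (whose central 95% ran from -0.02 to 0.084). Genes of 1 cell type vary together, so this shows a shared T and NK signal and adds no horses (5 of 6 lower, exact sign-flip p = 0.0625). A larger share of macrophages diluting all other types alike stays open. The list's difference from the mean of the neutrophil, B cell and epithelial lists (themselves at -0.029) was -0.26 ± 0.236 (SD over 6 horses), with exact sign-flip p = 0.09375. This comparison says little about dilution, since it leaves out the mast cell and dendritic cell lists, which were lower (-0.60 and -0.18). Many genes it used were also dim, with 7 of 14, 7 of 15 and 11 of 27 above the median level of all probes.

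The lower mast cell, basophil and eosinophil list could likewise reflect fewer such cells. A second list of 14 measured mast cell and basophil genes had a mean of -0.047 ± 0.153 (SD over 6 horses), with 11 lower, 1 at an unadjusted p under 0.05. It lay at percentile 18.1 of matched random lists, which neither meets nor excludes that explanation. Picked out after their values were seen, CD200R1 was at 0.52 and SLC18A2 at -0.503, so single genes weighed heavily in this mean. Of the first list, 6 of 11 genes lay above the median level of all probes, and 1, FCER1A, is shared with the dendritic cell list.

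The 669 probes for olfactory receptors, which are known from the nasal epithelium, belong to none of the 32 lists and were picked out after their values were seen, because many were lower at T1. Their median shift was -0.093, with 115 lower and 5 higher at an unadjusted p under 0.05 and all 6 horses lower, and it was -0.0622 after quantile normalization and -0.0572 after median centring, with 5 of 6 horses lower in both. A fall of all dim probes stays open: although 0 of 10000 random lists matched on level had a median as low (typically -0.035), with time points swapped within horses 24 of the 31 other assignments also put this family outside all of 1000 matched lists, so its probes vary together from array to array. A fall shared with other single-exon receptors stays open too, since 33 taste and vomeronasal receptor genes had a mean of -0.047 ± 0.039 (SD over 6 horses), lower in 5 of 6 horses (exact sign-flip p = 0.0625), although their median of -0.0287 lay at percentile 61.8 of random lists matched on level and, against a family picked out for being low, at percentile 98.7 of matched olfactory receptor lists. These comparisons are across genes and add no horses, and no biological explanation was tested.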

How the results depend on the processing

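The pair of alternatives chosen after seeing the data (repeated probes once, named genes only) left 0 probes past adjusted p 0.05, as did every other setting at that threshold with all 6 horses except the mean over a gene's probes, fitted to 16661 named genes, where MIR223 alone passed. Counts ran from 0 to 15 when a horse was left out, and the cause was not tested. There was 1 probe without horse 1 (MIR223), and there were 15 without horse 5 (3 higher, 12 lower, 1 of them named, MIR223). A pair of the unnamed lower probes gave the same difference, -1.069 without horse 5, and may repeat 1 measurement. Under unadjusted p under 0.05 with at least 1.5-fold change, 268 probes passed. Without the horse block 2062 probes had an unadjusted p under 0.05 and 6 lists passed; with the horse as a random effect, 3900 and 8. Leaving out the dimmest probes gave 6 lists, and leaving out a horse 5 (without horse 3) to 13 (without horse 5). With an estimated correlation, by fry's one-way form and by the exact sign-flip test 0 lists passed. Each of these allows for members that vary together. The sign-flip test, with a smallest p of 0.03125, can bring a list past the threshold after adjustment only if many lists reach that p. Under these tests adjusted p was 0.642, 0.37 and 0.417 for T and NK cells and 0.642, 0.379 and 0.417 for the mast cell list. Fry's mixed form passed 4 lists, with adjusted p = 0.034 for T and NK cells and 0.0701 for the mast cell list. Both lists kept their direction and passed camera in the 13 settings that kept the preset test, with adjusted p of 7.23e-22 to 1.07e-09 and 4.85e-08 to 0.000138.

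The other 8 list calls each ended when some horse was left out, as given above beside each list. Without the block adjusted p was 0.119 for NF-kappaB, 0.0529 for antioxidant genes, 0.0725 for the unfolded protein response and 0.0505 for lipid genes. With the random effect it was 0.0878 for NF-kappaB and 0.0561 for the unfolded protein response, and after quantile normalization 0.112 for the unfolded protein response and lipid genes. Without the dimmest probes it lay between 0.0627 and 0.0659 for phagocytosis, antioxidant, unfolded protein response and lipid genes, and array weights gave 0.0834 for NF-kappaB. Lists past camera only under some setting were immediate early genes (0.0404 after quantile normalization, 0.0223 without horse 5), cholesterol synthesis (0.0274 without horse 2, 0.00215 without horse 4), epithelium (0.0257 without horse 5, 0.026 without horse 6), lysosome (0.0364 without horse 1), pattern recognition (0.0243 without horse 2), and the cytokine and interferon lists as given above.

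Shifts near 0 turned sign; the cause was not tested. Quantile normalization gave NADPH oxidase -0.0133 and cell cycle 0.0166. Median centring, which moves the median difference of all probes from -0.0093 to 0.026, gave MHC class II 0.00857, hypoxia 0.029, heat shock 0.0312 and cell cycle 0.0349. Without the dimmest probes cell cycle was 0.0141, and array weights gave NADPH oxidase -0.00834, glucocorticoid response -0.00312 and cell cycle 0.00996. Leaving out a horse gave heat shock -0.0136 to 0.00689, hypoxia -0.0466 to 0.0228, cell cycle -0.0433 to 0.0553, MHC class II -0.0538 to 0.00963, NADPH oxidase -0.0198 to 0.0296, glucocorticoid response -0.0225 to 0.0212 and cholesterol synthesis -0.139 to 0.00509. The 99 named genes gave 1382 values over all settings, 0 of them reversed and 3 past adjusted p 0.05, each of them MIR223. The lack of reversals says little, since these genes were picked from the same data by smallest p. Those named over all probes also had to move one way in every horse. When some horse was left out, 21 of the 99 genes, and 24 of the 32 lists, moved by over 1.5 times. Signal over background is unknown, so no floor can be given for dim probes.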

Other observations

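The counts over swapped time points in this part were chosen after the results were seen, except those of gene lists and of probes moving one way. For the T and NK list the count restates its planned exact sign-flip test. The genes in the next paragraph were also chosen after their values were seen, by function, from the 30 largest differences among named genes with an unadjusted p under 0.05, and larger differences were passed over. None passed the adjusted threshold.

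MMP3, the protease stromelysin, was at 1.55 (SE 0.468, adjusted p = 0.27) and higher in 5 of 6 horses, from -0.37 in horse 1 to 3.83 in horse 5. MMP12, macrophage elastase, was at 1.02 (SE 0.431), with -1.01 in horse 1 and 2.83 in horse 5. EREG, the growth factor epiregulin, was at 1.21 (SE 0.388), the serpin SERPINB10 at 1.24 (SE 0.379) and the monocyte-attracting chemokine CCL15 at 0.79 (SE 0.228), which was higher in 6 of 6 horses. On the lower side, the chemokines CXCL9 (-1.25) and CXCL11 (-0.92) were at -3.28 and -2.80 in horse 4 and at -2.38 and -1.90 in horse 3, but at 0.31 and 0.26 in horse 5. KIT, the stem cell factor receptor of mast cells (-1.05), and HRH4, a histamine receptor (-1.10), were furthest down in horses 2 and 4, at -2.08 and -2.92 for KIT and -3.61 and -1.69 for HRH4.

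Time points were swapped within horses in all 32 distinct ways, the real one included. Of these, 1, the real one itself, gave as many probes at an unadjusted p under 0.05 as the real assignment (3970, with 2770 the highest of the others). For probes moving one way in all 6 horses it was also 1, the real one (2251, with 1556 the highest of the others). Both counts thus exceeded every swapped assignment. But 1 of 32 is the smallest share possible. The count at an unadjusted p under 0.05 was chosen after the results were seen, so chance is not excluded for it. The count of probes moving one way was planned, but its threshold was set later, so its 1 of 32 speaks only weakly against chance. For lower olfactory receptor probes the number of such assignments was also 1, the real one (115, with 95 the highest of the others). That excludes nothing, since the family was picked out for being lower. Chance is not excluded either for the number of gene lists past camera, where 14 of the 32 gave 10 or more and the highest other gave 17. Nor is it excluded for the mean shift of the T and NK list, where 2 of the 32 gave a shift as large (0.2885 in size, with 0.3046 the highest other). The number of probes past adjusted p 0.05 was 0, which all 32 match by necessity (1 was the highest other), so it says nothing about chance. The many lists called in swapped assignments are a sign that list members vary together from array to array. In the second list of T and NK genes, the smallest p belonged to SATB1 (-0.62), SLA2 (-0.34) and PRKCQ (-0.45), chosen after their values were seen.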
